A study of Oscheius tipulae with 48 samples.

How the data were processed

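Total RNA of embryos and whole worms was depleted of ribosomal RNA and made into libraries with a total RNA kit, per the labels' protocols. Embryos were obtained by bleaching worms that carried eggs and developed at 25 °C, and L1 larvae that had arrested without food were plated on bacteria and grown at 20 °C, per the labels' protocols. The authors deposited 1 table of RPKM values, reads scaled by gene length and by library size, with 14558 gene IDs and 48 library columns; the unit was taken from the values, which are not whole and sum to different totals. The submitters' processing notes list Bowtie2 2.4.2, STAR 2.7.10, StringTie 2.2.0 and HTSeq 2.0.2, with no role or order; the genome build and annotation are not given in the sources used here. The file does not pair gene IDs with names, so genes are given by ID, with at most 2 higher and 2 lower per comparison. Lists of named genes and the set of genes near chromosome ends, both fixed before the data were examined, need names or coordinates and were not analysed here. Reads shared between near-identical genes and overlapping genes cannot be told apart from these values.

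Libraries were grouped by the stage in their labels. The columns of L2, L3 and L4 carry other replicate digits than the labels do, so these 6 libraries have no replicate number, and their column digit serves only as a name. Embryo replicate numbers are those of the library descriptions, which differ from the titles for 16-32 and 64-128 cells and for the single libraries of 2, 100-150 and 150-200 cells. No pair of the 1128 library pairs shared more than 0.468% of its values above 1 RPKM, so none was taken as the same library deposited in duplicate. The values give no read counts. In low values, 1 read leaves a step whose size falls with depth, and pairs of libraries were compared through these steps, directly and through mixed embryos. The 2 routes agreed within 3% for 32 of 46 libraries, whose depth lay between 0.388 and 4.50 times that of 2-4 cell replicate 2, up to a small whole factor. The lowest was that of post-dauer L3 replicate 1. Depth was not resolved for the others, among them dauer, post-dauer L4 and post-dauer young adult replicate 1. The number of libraries per group limits the precision of every comparison.

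Values were tested as log2(RPKM + 1) with limma 3.58.1 in R 4.3.3, with a mean-variance trend and robust empirical Bayes moderation. The 17 libraries of 6 replicated embryo stages formed 1 fit and the 25 libraries of 12 larval, dauer and adult groups another, each sharing 1 estimate of the spread. Genes with at least 1 RPKM in at least 2 libraries of the fit were kept, 9332 in embryos and 14446 in worms. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 and a log2 change of at least 1 in size. Such a fold change understates the change of low genes. Genes were named by a rule fixed before the data were examined: called genes whose groups do not overlap and whose mean in the higher group is at least 10 RPKM, the 2 of largest fold change in each direction. The difference of the post-dauer effect between stages was tested with a limma F-test. Lists of at most 500 called genes were tested with camera, with a preset correlation of 0.01 and with an estimated one, and with fry, whose adjusted p was at lowest 0.0963 over the 8 tests; the rest of the design was also fixed before the data were examined.

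In embryos the numbers pair the samples from 2-4 to 32-64 cells: over 10 pairs of stages with 3 shared numbers, the deviations of same-numbered libraries from their group means correlated across genes at 0.211 to 0.837. The pairing is less clear at 64-128 cells, a stage of 2 libraries. Its replicate 1 correlated in this way with the other libraries of that number at 0.084 to 0.310, and its replicate 3 at 0.372 to 0.626. The fit with the replicate number as a block gave 3270 genes between 2-4 and 32-64 cells, against 2289 without it.

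Alternatives were quantile normalization, no trend, no filter on low values, a pseudocount of 0.1, only the 2 groups compared in the fit, the replicate number as a block, and leaving out each library. A fit without 7 libraries that stood apart (L1, young adult, dauer, post-dauer L3, post-dauer L4 and post-dauer young adult replicate 1, and 16-32 cell replicate 3) and a fit with the median of silent genes subtracted from each library were chosen after seeing the data. The first of these fits kept dauer replicate 2, although the median of its silent genes was raised too. Where a library left out leaves 1 in its group, that library is assumed to vary like the other groups.

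The functions were tested on simulated data. With 100 genes changed by each size between 32-64 and 2-4 cells, 36% of those changed by 1.5 on the log2 scale and 91% of those changed by 3 were recovered among 8999 genes, with 4 false calls. Between males and mature adults the shares were 11% and 71% among 14406 genes, with 3 false calls. The changed genes were drawn only from those with a mean log2(RPKM + 1) above 3 in the reference group. The simulated noise was independent between genes and between libraries. These shares and false calls therefore do not carry over to lower genes, or to real libraries whose genes or replicates vary together. Figures and checks of libraries were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.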

Results

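RNA-seq was used to follow gene expression through the life cycle of Oscheius tipulae, a free-living nematode that removes parts of its chromosomes during early embryogenesis. The 48 libraries of strain CEW1 fell into 23 groups. Staged embryos gave 9 groups, from 2 cells to 150-200 cells, of which 6 held 2 or 3 libraries and 3 held a single library. Directly grown worms gave L1, L2, L3 and L4 larvae, young adults and mature adults. Dauer larvae, the arrested stress-resistant larval form, gave 1 group, and worms recovered from dauer gave post-dauer L3, L4, young adult and mature adult groups. Adult males were hand-picked from a him-1(sy527) mutant, 200 per library. Each of these larval, dauer and adult groups held 2 libraries except L1, which held 3. Mixed embryos (1 library) and mixed worms (2 libraries) entered no comparison. Values were RPKM for 14558 genes, known here by ID alone. They summed to between 371389 RPKM in dauer replicate 2 and 860569 RPKM in 16-32 cell embryo replicate 3. The titles call replicates biological and say nothing more of separate cultures, so the p-values below measure the spread between these libraries, part of which may be technical. Counts of changed genes are genes past a Benjamini-Hochberg adjusted p of 0.05 in limma with a log2 change of at least 1 in size, and log2 changes are on the log2(RPKM + 1) scale. Without any difference, a share of about 0.05 of the genes tested would reach an unadjusted p under 0.05. Where fewer did, limma may have been too strict, and a count of 0 does not show that groups are alike.

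Several libraries stood apart from others of their group. The 3124 genes with a median under 0.5 RPKM across all libraries had a median of 5.32 RPKM in post-dauer young adult replicate 1, 3.59 RPKM in dauer replicate 1, 2.44 RPKM in post-dauer L3 replicate 1, 1.55 RPKM in dauer replicate 2 and 1.37 RPKM in post-dauer L4 replicate 1. In the other 43 libraries this median was between 0 and 0.54 RPKM. L1 replicate 1 correlated across genes at r = 0.756 and 0.770 with the other L1 libraries and at 0.879 with the 150-200 cell embryos, whereas L1 replicates 2 and 3 correlated at 0.921. Young adult replicates correlated at 0.827, and post-dauer young adult replicates at 0.596, the lowest of 31 pairs of libraries of 1 group. Genes are not independent replicates, and these correlations describe libraries only. Among 44 libraries with a replicate, 29 correlated more closely with a library of another group than with their own.

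**Figure D1:**
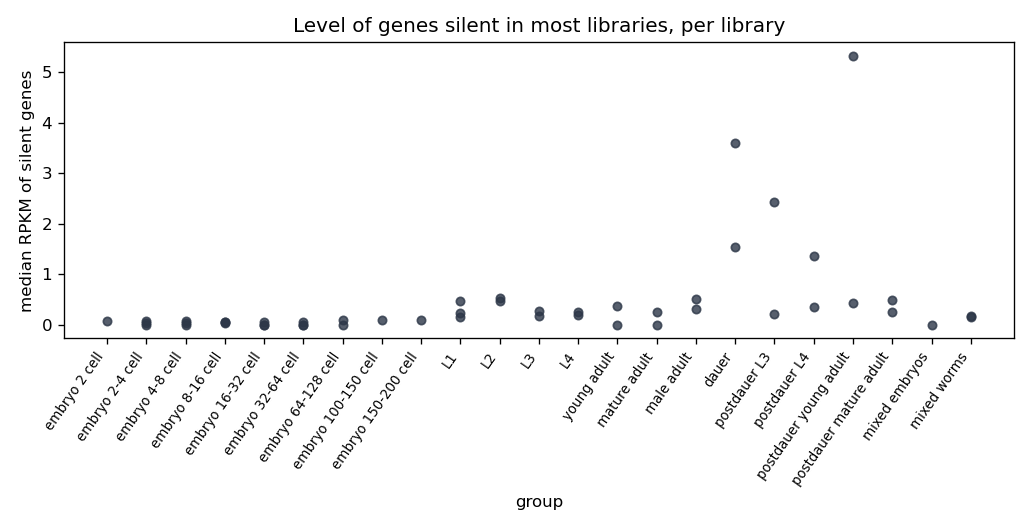
Median RPKM (linear axis) of the 3124 genes that were under 0.5 RPKM at the median of all libraries, 1 point per library, by group. Post-dauer young adult replicate 1 lay highest at 5.32 RPKM, and 43 of the libraries lay at or below 0.54 RPKM.

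In embryos, the first comparison asked how the transcript pool changed between 2-4 cells and 32-64 cells, across the window of DNA elimination that the series names. Oti_g14031 rose from 15.4 ± 18.8 RPKM at 2-4 cells to 162 ± 44.7 RPKM at 32-64 cells (SD, n = 3 each), a log2 change of 3.95 ± 0.63 (SE). Oti_g00783 rose from 186 ± 214 to 2660.4 ± 2846 RPKM (SD, n = 3 each), a log2 change of 3.88 ± 1.10 (SE). Oti_g03507 fell from 242 ± 98.1 to 51.3 ± 25.6 RPKM and Oti_g10268 from 40.3 ± 22.7 to 8.86 ± 7.95 RPKM (SD, n = 3 each), log2 changes of -2.28 ± 0.54 and -2.26 ± 0.72 (SE). The limma Benjamini-Hochberg adjusted p values of these 4 genes were 0.00154, 0.0187, 0.00699 and 0.0289. In all, 1834 genes were higher and 455 lower at 32-64 cells among 9332 tested. With the replicate number as a block, which pairs the embryo libraries, 2559 were higher and 711 lower. The values of the 4 genes and both lists come from the fit without the block. The 455 early genes had a library median of 68.8 ± 11.9 RPKM at 2-4 cells and 25.1 ± 7.49 RPKM at 32-64 cells (SD, n = 3 each), and the 1834 later genes 3.02 ± 2.15 RPKM (SD, n = 3) and 9.97 to 24.9 RPKM over the 3 libraries. These lists were chosen on the same libraries, so their levels at those 2 stages are not independent evidence of direction. The same holds for each list below in the groups that defined it. The median log2 change of all genes was 0.33, and after quantile normalization, which moved that median to -0.07, the split was 1134 higher and 1075 lower. The count was 1022 without 2-4 cell replicate 1, 1306 without 2-4 cell replicate 2, 1297 without 32-64 cell replicate 2 and 1129 without 32-64 cell replicate 3. The call of Oti_g00783 was lost without any 1 of these 4 libraries, and that of Oti_g10268 without any but 2-4 cell replicate 2 and with no filter on low values.

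**Figure D2:**
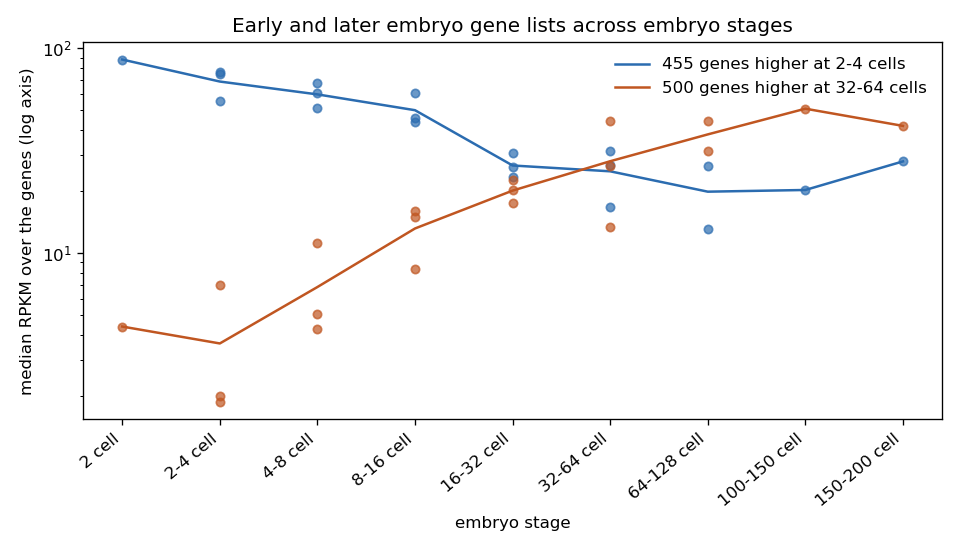
Median RPKM (log axis) over the 455 genes higher at 2-4 cells and over the 500 of largest change among the genes higher at 32-64 cells, by embryo stage; points are libraries and lines join group means. The early list lay at 88.2 RPKM in the single 2-cell library and the later list at 50.7 RPKM in the single 100-150 cell library.

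Between neighbouring embryo stages no gene passed the limma threshold. The counts were 0 from 2-4 to 4-8 cells, 4-8 to 8-16 cells, 8-16 to 16-32 cells, 16-32 to 32-64 cells and 32-64 to 64-128 cells. At an unadjusted p under 0.05, limma gave 186, 108, 900, 70 and 60 genes in these 5 steps. All but the 900 are a smaller share than 0.05 of the genes tested, so these 0 calls do not show that neighbouring stages are alike. With the replicate number as a block, limma also called 0 in each, with 689, 764, 2285, 287 and 792 genes at that unadjusted p. The block pairs the embryo libraries, though less clearly at 64-128 cells. After quantile normalization the calls were again 0, with 178, 185, 1215, 177 and 186 genes at that unadjusted p. The levels of Oti_g14031 were 36.3 ± 26.4 RPKM at 4-8 cells and 86.3 ± 28.0 RPKM at 8-16 cells (SD, n = 3 each). Those of Oti_g03507 were 182 ± 76.4 and 132 ± 51.4 RPKM (SD, n = 3 each) at these stages.

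Of 14446 genes tested with limma, 313 were higher and 0 lower in L2 than in L1, with 1499 genes at an unadjusted p under 0.05 in both directions together. The protocols plate L1 larvae that had arrested without food on bacteria, so feeding may differ along with stage. Oti_g07950 rose from 0.483 ± 0.381 RPKM (SD, n = 3) in L1 to 653 ± 252 RPKM (SD, n = 2) in L2, and Oti_g03588 from 0.873 ± 0.426 RPKM (SD, n = 3) to 714 ± 125 RPKM (SD, n = 2). Their log2 changes were 8.76 ± 2.22 and 8.59 ± 1.97 (SE), with limma Benjamini-Hochberg adjusted p values of 0.0482 and 0.0275. The 313 genes had a library median of 1.27 ± 0.392 RPKM in L1 and 26.6 ± 3.34 RPKM in L2, and a median of 20.8 ± 3.46 RPKM in L3 and 21.5 ± 0.0990 RPKM in L4 (SD, n = 3 for L1 and 2 for the others). Without L1 replicate 2 the count was 174, without L2 replicate 1 it was 1 and without L2 replicate 2 it was 25, and both named genes lost their calls without any 1 of the 5 L1 and L2 libraries. With the libraries that stood apart left out, L1 replicate 1 among them, 697 genes were higher and 54 lower in L2. The count was 107 after quantile normalization and 128 with only these 2 groups in the fit. With a pseudocount of 0.1, 118 genes were higher and 1 lower in L2.

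From L2 to L3, limma called 0 genes, with 173 at an unadjusted p under 0.05, 39 called when only these 2 groups entered the fit and 0 after quantile normalization. From L3 to L4, Oti_g08763 was the single gene called, at 16.1 ± 6.59 RPKM in L3 and 0.425 ± 0.148 RPKM in L4 (SD, n = 2 each), a log2 change of -3.53 ± 0.49 (SE, limma Benjamini-Hochberg adjusted p = 0.0115). That call was lost without any 1 of the 4 L3 and L4 libraries, each of which left 0 genes, and after quantile normalization 2 genes were higher and 2 lower in L4. With only these 2 groups in the fit 5 other genes were higher and 2 lower, and Oti_g08763 was not called (limma Benjamini-Hochberg adjusted p = 0.0799), nor with a pseudocount of 0.1 (limma Benjamini-Hochberg adjusted p = 0.199).

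Passage from L4 to young adult lowered 152 genes and raised 35. Oti_g01248 was at 8354 ± 194 RPKM in L4 against 2.63 ± 1.69 RPKM in young adults (SD, n = 2 each), a log2 change of -11.25 ± 1.47 (SE). Oti_g12261 was at 416.05 and 501.57 RPKM in the L4 libraries and at 0 and 2.91 RPKM in the young adults. Oti_g13486 rose from 42.1 ± 32.3 to 1489 ± 185 RPKM and Oti_g12628 from 1.13 ± 0.389 to 79.6 ± 49.9 RPKM (SD, n = 2 each), log2 changes of 5.34 ± 1.03 and 5.10 ± 0.81 (SE). In limma, Benjamini-Hochberg adjusted p values were 0.00159, 0.00086, 0.0211 and 0.00735 in that order. Outside this comparison, the 35 genes that rose had a library median of 40.6 ± 5.49 RPKM in mature adults and 4.98 ± 1.40 RPKM in males (SD, n = 2 each). The count of 187 was 3 without L4 replicate 1, 5 without L4 replicate 2, 7 without young adult replicate 1 and 1175 without young adult replicate 2. It was 71 after quantile normalization, with 23 higher and 48 lower, and 600 without the libraries that stood apart, with 486 higher and 114 lower. With a pseudocount of 0.1 it was 9, with 0 higher, and with only these 2 groups in the fit limma called 0, with 3276 genes at an unadjusted p under 0.05. The call of Oti_g01248 was lost without L4 replicate 1, and those of Oti_g13486 and Oti_g12628 without either L4 replicate or young adult replicate 1.

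Between young and mature adults limma called 0 genes, with 498 at an unadjusted p under 0.05, 0 called after quantile normalization and 1 with a pseudocount of 0.1. Oti_g12875 was at 638.68 and 1737.96 RPKM in the young adults and at 9839.68 and 3026.23 RPKM in the mature adults. Without young adult replicate 2 the count was 94.

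Gene lists defined in one comparison were followed in comparisons made of other libraries. Early embryo genes, the 455 higher at 2-4 cells, were higher in young adults than in L4, with a median log2 change of 1.57 against -0.15 for other genes (camera in limma, Benjamini-Hochberg adjusted p = 4.4e-43 over 8 list tests). Of these 455 genes 3 were called on their own over all genes and 0 when adjusted over the list alone, and the adjusted p was 0.279 with an estimated correlation. In mature against young adults the same list had a median log2 change of 0.23 and other genes -0.17 (camera in limma, Benjamini-Hochberg adjusted p = 2.55e-13), with an adjusted p of 0.381 with an estimated correlation. That median was 0.10 without young adult replicate 2 and 0.11 without mature adult replicate 1, and neither passed (adjusted p = 0.160 and 0.233 with camera in limma and Benjamini-Hochberg adjustment), and it was 0.38 without young adult replicate 1 and 0.36 without mature adult replicate 2. Later embryo genes, the 500 of largest change, had median log2 changes of -0.72 in young adults against L4 and -0.62 in mature against young adults (camera in limma, Benjamini-Hochberg adjusted p = 8.01e-10 and 4.04e-14). With an estimated correlation the adjusted p was 0.279 for both, and 2 and 0 genes were lower when adjusted over the list alone. In mature against young adults the median was -0.18 without mature adult replicate 1 and -1.04 without mature adult replicate 2.

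Male genes, the 500 with the largest excess in him-1(sy527) males over mature adults, a list in which sex and genotype are not separated, had median log2 changes of 0.15 in L4 against L3, 1.23 in young adults against L4 and 1.04 in post-dauer L4 against post-dauer L3. With camera in limma the Benjamini-Hochberg adjusted p values were 0.00941, 1.31e-19 and 6.63e-19, and with an estimated correlation the adjusted p values were 0.709, 0.279 and 0.279. No gene of this list was called on its own in these 3 comparisons, nor when adjusted over the list alone. The libraries of these groups differed in the list: its median was 0 and 7.52 RPKM in young adult replicates 1 and 2, 3.06 and 0 RPKM in post-dauer L3, 1.82 and 6.87 RPKM in post-dauer L4, and 0.340 and 4.4 RPKM in mature adults. In replicate 1 of post-dauer L3 and L4 the silent genes themselves had the raised medians of 2.44 and 1.37 RPKM given above. In young adults against L4 the median log2 change was 2.51 without young adult replicate 1 and -0.25 without replicate 2. In L4 against L3 it was 0.27 without L3 replicate 1 and did not pass (camera in limma, Benjamini-Hochberg adjusted p = 0.0808). In post-dauer L4 against post-dauer L3 it was 1.94 and 0.16 without post-dauer L3 replicates 1 and 2, and 1.73 and 0.35 without post-dauer L4 replicates 1 and 2. The 71 genes higher in dauer than in post-dauer L3 had a median log2 change of 0.22 in L1 against L2 (camera in limma, Benjamini-Hochberg adjusted p = 2.62e-06), with an adjusted p of 0.279 with an estimated correlation and 0 genes called when adjusted over the list alone. That median was 0.01 without L1 replicate 2 and 0.42 without L1 replicate 3.

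Dauer larvae differed from L3 larvae in 432 genes, of which 147 were higher and 285 lower. Oti_g10670 was at 579.29 and 99.8 RPKM in the dauer libraries and at 0.11 and 2.02 RPKM in L3, a log2 change of 7.05 ± 1.01 (SE). Oti_g10891 was at 178.4 and 69.14 RPKM in dauer and at 0 and 0.44 RPKM in L3, a log2 change of 6.55 ± 0.93 (SE). Oti_g13334 fell from 2337 ± 472 RPKM in L3 to 4.64 ± 1.42 RPKM in dauer and Oti_g00361 from 1587 ± 486 to 5.93 ± 0.127 RPKM (SD, n = 2 each), log2 changes of -8.70 ± 1.87 and -7.81 ± 1.95 (SE). The limma Benjamini-Hochberg adjusted p values were 0.00156, 0.00155, 0.0264 and 0.0418. The 285 genes lower in dauer had a library median of 56.9 ± 2.64 RPKM in L2, 56.6 ± 2.66 RPKM in L4 and 38.9 ± 0.983 RPKM in post-dauer L3 (SD, n = 2 each). Both dauer libraries carried the raised level of silent genes given above, and with that level subtracted the split was 183 higher and 1098 lower. The count was 15 and 18 without L3 replicates 1 and 2, 13 and 40 without dauer replicates 1 and 2, 1136 after quantile normalization and 125 with a pseudocount of 0.1. Oti_g13334 and Oti_g00361 lost their calls without any 1 of these 4 libraries, Oti_g10670 without L3 or dauer replicate 1 and Oti_g10891 without dauer replicate 1. With only these 2 groups in the fit 2657 genes were higher and 2002 lower. The fit without the libraries that stood apart kept dauer replicate 2, with its raised level, as the only dauer library. The median log2 change of all genes was 0.14 with all libraries and -0.11 in that fit.

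On recovery from dauer, post-dauer L3 larvae had 101 genes higher and 71 lower than dauer larvae. Oti_g12119 rose from 4.05 ± 1.00 to 524 ± 302 RPKM and Oti_g11997 from 5.37 ± 0.757 to 445 ± 120.1 RPKM (SD, n = 2 each), log2 changes of 6.58 ± 1.17 and 6.11 ± 1.10 (SE). Oti_g10670, higher in dauer than in L3, was at 5.89 and 0.48 RPKM in post-dauer L3, a log2 change of -6.24 ± 1.01 (SE), and Oti_g09256 fell from 447 ± 171 to 5.71 ± 0.502 RPKM (SD, n = 2 each), a log2 change of -6.01 ± 0.94 (SE). For these 4 genes the limma Benjamini-Hochberg adjusted p values were 0.0122, 0.0136, 0.00668 and 0.00543. The 101 genes that rose had a library median of 51.3 ± 16.4 RPKM in post-dauer L3 and 43.4 ± 1.93 RPKM in L3 (SD, n = 2 each). The count was 6 and 24 without dauer replicates 1 and 2, 20 and 81 without post-dauer L3 replicates 1 and 2, 1058 after quantile normalization, 1005 with only these 2 groups in the fit, 1121 without the libraries that stood apart and 27 with a pseudocount of 0.1. Oti_g12119 and Oti_g11997 lost their calls without any 1 of these 4 libraries, Oti_g10670 without dauer replicate 1 or post-dauer L3 replicate 2 and Oti_g09256 without dauer or post-dauer L3 replicate 1. With the raised level subtracted the split was 528 higher and 168 lower, and with the replicate number as a block it was 13 higher and 22 lower. The fit without the libraries that stood apart kept dauer replicate 2, with its raised level, as the only dauer library.

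**Figure D3:**
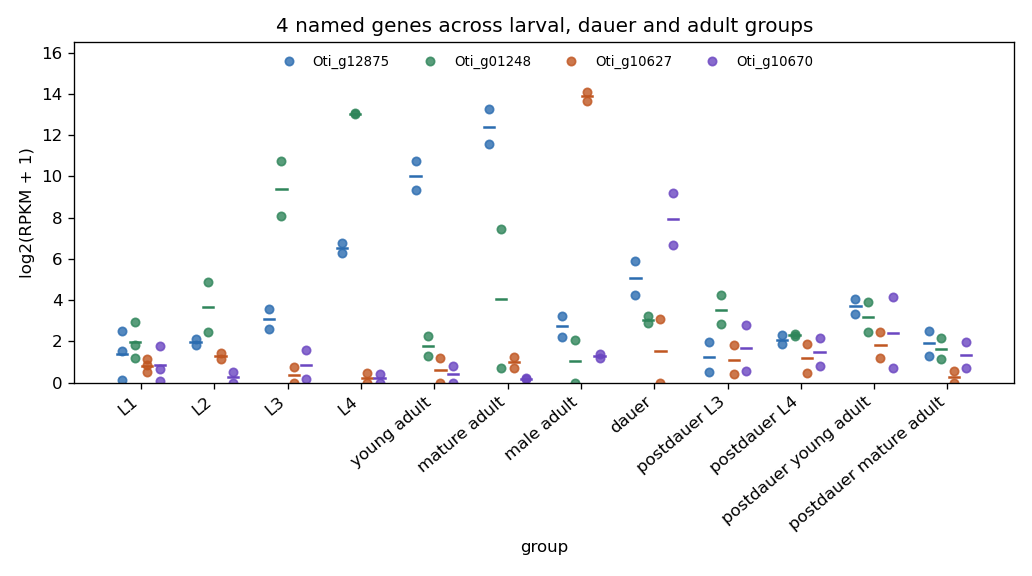
log2(RPKM + 1) of 4 named genes in 12 larval, dauer and adult groups; points are libraries and bars are group means. Oti_g01248 lay highest in L4 larvae (8354 RPKM), Oti_g12875 in mature adults (6433 RPKM), Oti_g10627 in males (15299.7 RPKM) and Oti_g10670 in dauer larvae (339.5 RPKM).

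Worms recovered from dauer were then compared with directly grown worms of the stage of that name. Whether libraries of the same stage name were at the same point of development was not tested. In L3, limma called 0 genes, with 279 at an unadjusted p under 0.05, 2 called after quantile normalization and 0 when only these 2 groups entered the fit. These 279 are a smaller share of the genes tested than 0.05, so the 0 does not show that the groups are alike. In L4, 33 genes were higher and 94 lower in post-dauer worms. Oti_g01248 was at 3.88 ± 0.240 RPKM in post-dauer L4 against 8354 ± 194 RPKM in L4, and Oti_g12261 at 0.315 ± 0.021 against 459 ± 60.5 RPKM (SD, n = 2 each), log2 changes of -10.74 ± 1.47 and -8.44 ± 0.90 (SE). Oti_g08406 was higher, at 462.18 and 57.18 RPKM against 0.88 and 1.11 RPKM, a log2 change of 6.36 ± 0.94 (SE), and Oti_g08405 was at 142.5 and 11.48 RPKM against 0.03 and 0 RPKM. The limma Benjamini-Hochberg adjusted p values were 0.00186, 0.000143, 0.00359 and 0.0303. Against the same L4 libraries, Oti_g01248 and Oti_g12261 were also lower in directly grown young adults, with log2 changes of -11.25 and -7.86. Outside their group, post-dauer L4 replicate 1 was closest to post-dauer mature adult replicate 1 (r = 0.928). Replicate 2 was closest to post-dauer young adult replicate 2 (r = 0.935). A later point of development than that of the L4 libraries therefore cannot be told apart here from an effect of dauer. The 94 lower genes had a library median of 17.3 ± 9.87 RPKM in post-dauer L3 and 1.92 ± 0.0955 RPKM in post-dauer L4 (SD, n = 2 each). The count was 2 without either L4 replicate, and 13 and 28 without post-dauer L4 replicates 1 and 2. Oti_g01248 lost its call without either L4 replicate, and Oti_g08406 and Oti_g08405 without either of these or post-dauer L4 replicate 1. Without the libraries that stood apart 438 genes were higher and 378 lower, with only these 2 groups in the fit 91 and 370, and with a pseudocount of 0.1 the split was 11 and 16.

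In young adults 5 genes were lower and 0 higher after dauer with limma, with 3580 at an unadjusted p under 0.05 and a median log2 change of all genes of 0.59. With the silent-gene level subtracted that median was -0.18, and limma called 28 genes lower and 2 higher, with 2819 at an unadjusted p under 0.05. Without the libraries that stood apart the median was 0.10. The 0.59 therefore depended on the raised silent-gene level. Oti_g07521 was at 15.9 ± 8.52 RPKM in post-dauer young adults and 1872 ± 772 RPKM in young adults, and Oti_g12875 at 12.4 ± 4.82 and 1188 ± 777 RPKM (SD, n = 2 each). Their log2 changes were -6.83 ± 0.90 and -6.34 ± 0.79 (SE, limma Benjamini-Hochberg adjusted p = 0.00291 and 0.00286). Without post-dauer young adult replicate 2, which leaves the library of the highest silent-gene level alone in its group, 5470 genes were called, without replicate 1 the count was 0 and both named calls were lost, and without young adult replicate 2 it was 212. After quantile normalization 29 genes were lower and 1 higher. With a pseudocount of 0.1 and with only these 2 groups in the fit limma called 0 genes, with 3271 and 363 at an unadjusted p under 0.05.

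Post-dauer mature adults had 577 genes higher and 107 lower than mature adults. Outside their group, post-dauer mature adult replicates 1 and 2 were both closest to post-dauer L4 replicate 1 (r = 0.928 and 0.917). A different point of development from that of the mature adults therefore cannot be told apart here from an effect of dauer. Oti_g12875 was at 1.44 and 4.7 RPKM in them against 9839.68 and 3026.23 RPKM, and Oti_g13559 at 0.95 and 4.3 against 9851.42 and 2143.46 RPKM, log2 changes of -10.52 ± 0.79 and -10.48 ± 0.89 (SE). Oti_g11075 was at 721 ± 199 RPKM in post-dauer mature adults and at 0 and 2.07 RPKM in mature adults, and Oti_g07062 at 833 ± 160 against 1.39 ± 1.64 RPKM (SD, n = 2 each), log2 changes of 8.66 ± 1.29 and 8.63 ± 1.12 (SE). The limma Benjamini-Hochberg adjusted p values were 9.57e-07, 3.47e-06, 0.00103 and 0.0005. The 107 lower genes had a library median of 36.3 ± 4.27 RPKM in mature adults and 35.0 ± 1.09 RPKM in mixed worms (SD, n = 2 each), and the 577 higher genes 18.9 ± 2.7 RPKM in dauer larvae (SD, n = 2). After quantile normalization the split was 114 higher and 92 lower, with only these 2 groups in the fit 648 and 505, and without the libraries that stood apart 2358 and 1029. The count was 59 without mature adult replicate 1, and 79 and 187 without post-dauer mature adult replicates 1 and 2.

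The post-dauer effect differed between the 4 stages for 21 genes (limma F-test, Benjamini-Hochberg adjusted p under 0.05), among 14446 tested. For Oti_g12875 the log2 change was -1.85 in L3, -4.46 in L4, -6.34 in young adults and -10.52 in mature adults, with an adjusted p of 0.0229 for the difference between stages in limma after Benjamini-Hochberg adjustment. In directly grown worms the mean of this gene was 93.0 RPKM in L4 and 6433 RPKM in mature adults. In post-dauer worms it was 3.265 RPKM in L4 and 3.07 RPKM in mature adults. A difference in the point of development between libraries of the same stage name cannot be told apart here from an effect of dauer. Leaving out 1 library gave 0 genes without L3 replicate 2, either L4 replicate or post-dauer mature adult replicate 1, 13 without L3 replicate 1, 6 and 58 without mature adult replicates 1 and 2, 35 and 559 without young adult replicates 1 and 2. It gave 75 without post-dauer L3 replicate 2, 5 without post-dauer L4 replicate 2, 41 and 1044 without post-dauer young adult replicates 1 and 2 and 12 without post-dauer mature adult replicate 2, and the count was 1376 without the libraries that stood apart.

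Males had 1173 genes higher and 97 lower than mature adults, the reference being whole worms of the mature adult stage. The males carried him-1(sy527) and the mature adults bear no such label, so sex and genotype cannot be told apart here. Oti_g10627 was at 17479.8 and 13119.6 RPKM in the male libraries against 1.38 and 0.65 RPKM, a log2 change of 12.90 ± 0.79 (SE). Oti_g11218 was at 6305.55 and 5997.75 RPKM in males and listed at 0 in both mature adult libraries. Oti_g07521 was at 4.31 ± 2.74 RPKM in males against 5754 ± 3956 RPKM, and Oti_g13559 at 4.18 ± 2.41 against 5997 ± 5450 RPKM (SD, n = 2 each), log2 changes of -9.99 ± 0.90 and -9.88 ± 0.89 (SE). With limma and Benjamini-Hochberg adjustment, p was 1.38e-08, 2.35e-08, 7.76e-07 and 7.95e-07. The 1173 male genes had a library median of 26.8 ± 0.361 RPKM in males and 0.710 ± 0.0849 RPKM in L4 (SD, n = 2 each). In mature adults that median was 1.93 ± 2.04 RPKM (SD, n = 2). After quantile normalization, which moved the median log2 change of all genes from 0.26 to -0.11, 755 genes were higher and 166 lower. The count was 156 without mature adult replicate 1, 622 and 604 without male replicates 1 and 2, 2925 without the libraries that stood apart and 610 with a pseudocount of 0.1.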

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

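The post-dauer effect differed between L3, L4, young adult and mature adult for 21 genes in a test fixed beforehand (limma F-test with Benjamini-Hochberg adjustment), and 5 of the named genes were among them. Oti_g12875, Oti_g13559 and Oti_g07521 had adjusted p values of 0.0229, 0.0229 and 0.0294 in limma, with log2 changes from -1.85, -1.44 and -1.73 in L3 to -10.52, -10.48 and -10.06 in mature adults. Oti_g12261 had an adjusted p of 0.0399 in limma, with log2 changes of -8.44 in L4 and -0.77 in young adults. In directly grown worms its mean was 459 RPKM in L4 and 1.455 RPKM in young adults. For these genes too, the point of development and an effect of dauer cannot be told apart. Oti_g08763 had an adjusted p of 0.0229 in limma, with log2 changes of -1.70 in L3 and 2.66 in L4, while post-dauer L3 against L3 called 0 genes in limma, with 279 at an unadjusted p under 0.05 and 2 called after quantile normalization.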

How the results depend on the processing

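Leaving out the libraries that stood apart and subtracting the silent-gene level were chosen after seeing the data. In embryos, the 5 steps between neighbouring stages stayed at 0 called genes under each alternative run, and the count between 2-4 and 32-64 cells was 1022 to 2781 when 1 library was left out. Counts of worm comparisons moved with most choices. Without the libraries that stood apart, the counts for males and for post-dauer against direct mature adults rose, though none of those libraries belongs to these groups. These rises therefore came from the spread shared over all groups and the genes kept, not from the values compared. The cause of the other moves was not tested. With quantile normalization they were 107 for L2 against L1, 4 for L4 against L3, 71 for young adult against L4, 1136 for dauer against L3, 1058 for post-dauer L3 against dauer, 2 for post-dauer L3 against L3, 30 for post-dauer against direct young adults and 206 for post-dauer against direct mature adults. A pseudocount of 0.1 gave, in the same order of comparisons, 1.2e+02 (to 2 digits), 0, 9, 125 and 27 for the first 5, with 27 for post-dauer against direct L4, 0 for post-dauer against direct young adults, 1 for mature against young adults and 610 for males. With only the 2 groups compared in the fit they were 128 for L2 against L1, 39 for L3 against L2, 7 for L4 against L3, 0 for young adult against L4, 4659 for dauer against L3, 1005 for post-dauer L3 against dauer, 461 for post-dauer against direct L4, 0 for post-dauer against direct young adults and 1153 for mature adults. Without the libraries that stood apart they were 751 for L2 against L1, 7 for L4 against L3, 600 for young adult against L4, 2918 for dauer against L3, 1121 for post-dauer L3 against dauer, 3, 816, 3 and 3387 for post-dauer against direct L3, L4, young adults and mature adults, 2925 for males and 1376 for the difference between stages. With the silent-gene level subtracted they were 5 for L4 against L3, 84 for young adult against L4, 1281 for dauer against L3, 696 for post-dauer L3 against dauer, and 2, 30 and 411 for post-dauer against direct L3, young adults and mature adults.

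Leaving out 1 library at a time gave 1 to 293 genes for L2 against L1, 0 for L4 against L3, 3 to 1175 for young adult against L4, 0 to 94 for mature against young adult, 13 to 40 for dauer against L3, 6 to 81 for post-dauer L3 against dauer, 2 to 28, 0 to 5470 and 59 to 686 for post-dauer against direct L4, young adults and mature adults, 156 to 1267 for males, and 0 to 1044 for the difference between stages. Of 33 calls of named genes, 11 stayed past the threshold in every refit run and 22 fell short in at least 1, and 0 turned direction. With 1 library left out 61 of 142 refits fell short, and under the other choices 28 of 249, of which 13 with a pseudocount of 0.1 and 10 with only the 2 groups in the fit.

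In worms no label ties the replicate numbers to a shared batch or day, and there are 2 pairs per comparison. Deviations of same-numbered libraries correlated at 0.314 between dauer and post-dauer L3 and at 0.606 between post-dauer L3 and post-dauer young adults. Between young and mature adults they correlated at 0.561, and other pairs of groups went down to -0.226. In dauer, post-dauer L3, post-dauer L4 and post-dauer young adults, replicate 1 carried the higher silent-gene level. A level shared in this way cannot be told apart from pairing in those groups. Whether the numbers pair the worm samples stays open. With the replicate block the counts were 35 for post-dauer L3 against dauer, with 13 higher and 22 lower, 3 for post-dauer against direct young adults and 242 for mature adults. For males the block gave 942 genes, of which 917 were among the 1270 without it. The block changed no call of a named gene that was run with it, in embryos or worms, and left the 5 embryo steps at 0 called genes. The 3 list tests that were run with the block, of male genes in post-dauer L4 against post-dauer L3 and of early and later embryo genes in mature against young adults, stayed past the threshold at the preset correlation of 0.01 (camera in limma), while fry in limma gave Benjamini-Hochberg adjusted p values of 0.538, 0.782 and 0.263 with the block. No paired analysis was possible for L2, L3 and L4 because their columns carry no label number, which also rules it out for the difference between stages.

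List tests lost their calls with an estimated correlation, which leaves their median log2 changes as they were: 0.15, 1.23 and 1.04 for male genes, 0.22 for dauer genes, 0.23 and 1.57 for early embryo genes, and -0.62 and -0.72 for later embryo genes. With all called genes as the list, male genes in L4 against L3 had a median log2 change of 0.0143 and were not called (camera in limma, Benjamini-Hochberg adjusted p = 0.385). Leaving out 1 library gave 0.10 to 0.27 for male genes in L4 against L3, -0.25 to 2.51 in young adults against L4, with the direction turned without young adult replicate 2, and 0.10 to 0.38 for early embryo genes in mature against young adults. The terminal gene alternatives at other distances were not run, since they need coordinates.

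The splits of 3 against 3 libraries are 10, too few for a share under 0.05. The real split of 2-4 and 32-64 cells gave 2289 genes and the highest other split 0, the other splits that part each pair of same-numbered libraries included. Of the 10 splits, 1 gave as many. Each other split mixes both stages in each of its groups, so a stage difference enters the spread and lowers the count. The 0 is therefore no measure of chance. In the 4 steps between neighbouring stages with 3 libraries each, the real and the highest other split were both 0, so that 10 of 10 gave as many.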

Other observations

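In single libraries and mixed samples, which entered no comparison, the early embryo genes had a median of 88.2 RPKM at 2 cells, 20.3 RPKM at 100-150 cells, 28.1 RPKM at 150-200 cells and 12.9 RPKM in mixed embryos. The later embryo genes, 500 by size of change, were at 4.38, 50.7, 41.8 and 30.9 RPKM in the same 4 libraries. In mixed worms, the 2 libraries had 3677 and 4848 RPKM of Oti_g12875, beside 0.21 RPKM in mixed embryos.

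All tests below on the raised level of silent genes except those on other stages' RNA (its first bound) and on genomic DNA, and all tests on runs of IDs, were chosen after the result was seen, the test of low depth was divided by library after it, and the 3 libraries not used to define the runs had been looked at before; the L1 tests were written before, except that the bootstrap interval was added after. The raised level of silent genes in 5 dauer and post-dauer libraries is argued against as low depth in 4 of them, where at most 1.02% of those genes were at 0, under the 5% set against it, although post-dauer L3 replicate 1 among them had the lowest relative depth resolved (0.388) and depth was not resolved for the other 3; dauer replicate 2, with 8.90%, stays open. RNA of another stage was tested on 132 genes under 0.5 RPKM in each of the other 43 libraries, whose median was as low as 0.377 of the silent-gene level (0.458 to 0.521 without 15 of them that lie in the runs of IDs described next), on the side of the bound (0.5) that this explanation allowed, but that bound was ill chosen, since a mixture cannot lift a gene above its highest level in the parts. Against that limit of 0.5 RPKM, the lower 95% bootstrap bound of the median was 0.535 RPKM or more in 4 libraries, which argues there against RNA of the stages held by those 43 libraries, dauer not being among them, and 0.400 RPKM in dauer replicate 2, which leaves it open. Dauer RNA carried into post-dauer young adult, L3 and L4 replicate 1 would bring the abundant transcripts of dauer. It was tested on 44 genes called higher in dauer than in L3. In post-dauer L3 and L4 replicate 1 they were at a median of 9.65% and 12.8% of their lower dauer level (upper 95% bootstrap bounds 13.8% and 19.8%). The raised level needs shares of 62.3% and 27.0%, which argues against carried-over dauer RNA there if it had the makeup of the dauer libraries. For post-dauer young adult replicate 1 the share needed was 157%, which no mixture can reach, since its level (5.32 RPKM) lies above that of dauer (at most 3.59 RPKM). The median of 37.8% there (upper bound 52.8%) therefore decides nothing. A first set of 4 genes, at 15.2%, 13.4% and 7.48% in post-dauer young adult, L3 and L4, was too small to decide. Genomic DNA may be a source, and would give silent genes about the same RPKM, but the 75th percentile was up to 2.38 times the 25th in the 2 libraries of highest level, between the bounds of 2 and 4 set for and against it, and passage through dauer stays open, untested, although 5 of the 8 post-dauer libraries lacked the raised level, with 0.21, 0.36 and 0.44 RPKM in replicate 2 of post-dauer L3, L4 and young adults and 0.49 and 0.25 RPKM in post-dauer mature adults.

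Genes that lacked the raised level in both post-dauer young adult replicate 1 and dauer replicate 1 (under 0.3 of it) numbered 173, and 81 of them lay in 8 runs of neighbouring IDs, 1 holding the first IDs and 1 the last, with 7 runs at bounds of 0.2 and 0.5. Among 10000 shuffles of the IDs 0 gave as many genes in runs (highest 8), which argues against chance order. In the 3 libraries of raised level not used to find them, the run genes had a median of at most 0.219 of that level, which is consistent with a hypothesis that DNA at these places is absent from the worms' cells, if the raised level comes from DNA and IDs follow the chromosomes; neither was tested. Genes that take no reads are argued against, since 0 of the 81 run genes were at 0 in all libraries or all but 1, but genes that take few reads stay open, since no more than 14 of the 81 reached 10 RPKM in an embryo library; the median of these 14 was 0.597 of the raised level in dauer replicate 2 and 0.061 in post-dauer L3 replicate 1. No run gene reached 10 RPKM in L2, L3 or L4 (0 genes), while at 150-200 cells their mean over genes was 59.2 RPKM, their median 0.47 RPKM and 37% of them at 1 RPKM or more. Their means were 4.91 RPKM at 2-4 cells, 6.53 RPKM at 4-8 cells, 10.6 RPKM at 8-16 cells and 5.23 RPKM at 16-32 cells. At 32-64 and 64-128 cells they were 27.9 and 39.5 RPKM. The share at 1 RPKM or more was 2.47% in L2 and in L3, 34.0% in young adults (mean 2.02 RPKM, median 0.72 RPKM), 24.7% in males and 19.8% in mature adults.

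L1 replicate 1 lay closer to embryos than to the other L1 libraries. An embryo library under a wrong label would leave L1 genes silent, but 334 genes at 20 RPKM or more in the other L1 libraries and under 2 RPKM in each embryo library had a median of 12.4% of their L1 level (95% bootstrap interval 10.6% to 14.6%), above the 10% bound by little. A mixture of L1 larvae and embryos may be a source: 87 embryo genes were at a median of 49.6% of their level at 64-200 cells, but the 2 shares sum to 62.0%, under the 70% that was asked for, so it stays open. Older embryos than those assayed here were not tested, nor was an earlier harvest.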
